A study of Sus scrofa with 16 samples.

How the data were processed

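Messenger RNA of pig (Sus scrofa) conceptuses, that is embryos with their extraembryonic membranes, was measured on 16 Affymetrix porcine GeneChips. Per the labels, gilts were mated naturally, their uteri were flushed with saline, and conceptuses were sorted by shape, frozen and extracted. Spherical conceptuses were 8 to 10 mm across on day 11, tubular ones were 20 to 80 mm long on days 11 and 12, and filamentous ones came from day 12 and day 14. There were 4 arrays per stage, and per the series design text each array carried its own pool of conceptus RNA. How many conceptuses or gilts made up a pool is not given in the sources used here, so p-values measure the spread between pools. All 16 columns were matched to their samples by label, and 0 columns were left unmatched.

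Per the series design text, the authors quantified the arrays with GCOS 1.1.1 and normalized and standardized them in dChip 1.3. The deposited values are on a log2 scale. The base is inferred from their range of 0 to 14.5 and is not stated in the sources used here. If the base were another, every fold given would change and the tests would not. Of 383984 values, 31 in 17 probe sets were exactly 0 and were kept. Dim probe sets, background and cross-hybridization between related genes were handled by the authors' software in a way the sources do not detail. The deposited log2 values were used without further normalization. The table carries no detection calls, and the number of arrays limits the precision. Near the largest value a change can be understated, so no folds are given for IL1B, IFNG, KRT8 and KRT18 where a stage lies at 14.0 or above, and folds of HSD17B1, GAPDH and GPX1, which come close to it, are uncertain. A fold against a stage far below the median level, as for MFSD4A and MUC4, rests on dim signal and is uncertain too. Below the median level (7.12) in every stage lay SPP1 (6.22 to 6.38), ISG15 (6.68 to 6.89), PTPRC (5.67 to 5.93) and HSD3B1 (6.74 to 7.06). Without detection calls, a lack of change in these genes may only reflect dim signal, and the HSD3B1 fold is uncertain.

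Of 24123 probe sets, 124 Affymetrix controls were left out and 23999 were tested. A platform annotation named 10069 of these with 1 gene symbol and 198 with several, and 13732 were not listed and stay unnamed here. No gene was named from a probe set with several symbols. The named probe sets covered 6765 symbols, of which 2261 had more than 1 probe set. The probe set with the highest mean stood for a gene, and a gene's probe sets can differ in the size of a change. Of 50 called gene results printed here with several probe sets, every probe set passed in 27 and some did not in 23. Passing log2 differences of a gene lay over 1.5 times apart in 19, and 0 of the 50 had probe sets passing in both directions. Among genes that the rule below names but that are not printed, PAG6 and NPC2 had such probe sets. PAG6 had 2 higher and 1 lower in day 12 filamentous against tubular and against spherical conceptuses. NPC2 had 1 higher and 1 lower in day 14 against day 12. Over all symbols 26, 27 and 17 had such probe sets in the comparisons after the first. No genome was used, so no coordinates are given. Probe sets of gene families such as the aromatases, the interleukin 1 beta copies and the pregnancy-associated glycoproteins can detect more than 1 family member, and their values are uncertain in that respect.

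A linear model with 4 stage means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with default empirical Bayes moderation (prior degrees of freedom 3.75). Tests were two-sided. Tubular was compared with spherical, day 12 filamentous with tubular, day 14 with day 12 filamentous, and day 12 filamentous with spherical. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 23999. A moderated F test covered any difference among the stages. Errors beside log2 differences are standard errors of the model, intervals of folds are 95% intervals, and n is 4 arrays per stage throughout. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

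The comparisons, tests, alternatives and 22 gene lists were fixed before the data were examined. The lists covered steroid synthesis, cholesterol, prostaglandins, interleukin-1 and NF-kappa B, interferons, growth factors, cytoskeleton, adhesion and matrix, matrix proteases, cell cycle, glycolysis, oxidative phosphorylation, ribosomal proteins, oxidant defence and hypoxia, retinoid, folate, iron and amino acid handling, and markers of trophoblast, epiblast, hypoblast, mesoderm, blood and endothelium, maternal leukocytes and uterus. Each list was tested in each of the 4 comparisons with limma's camera at a preset correlation of 0.01, and the 88 tests were adjusted together. With a correlation estimated from the data, 0 of the 19 called shifts passed, and that adjusted p stands beside each call. The estimate comes from 16 arrays.

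The rule for named genes was also fixed beforehand. For each comparison it took the 10 largest rises and 10 largest falls among called probe sets with 1 symbol, no overlap between the stages' arrays and a brighter stage at or above the median of all mean levels (7.12). For each list and comparison it took up to 4 called members with the smallest p in the more frequent direction and 1 in the other. It also took a panel of 23 genes, of which 21 were on the array with 1 symbol. The genes printed are part of those the rule names and were picked from them after their values were seen. For spherical and tubular conceptuses the rule was also applied to the fit with pairs as a block.

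Labels number the replicates 1 to 4 in every stage. Whether equal numbers pair the arrays was checked from the correlation of deviations from the stage means, before calls were compared. Between spherical and tubular arrays all 4 same-numbered correlations exceeded 0.1 (0.12 to 0.392, mean 0.248, against -0.0829 for unequal numbers), and 7 of 8 arrays correlated best with their own number. The labels do not say what the numbers share. In the other comparisons at most 1 of 4 pairs exceeded 0.1. Outside the comparisons made, 3 of 4 pairs exceeded 0.1 between spherical and day 14 arrays (mean 0.132) and between tubular and day 14 arrays (mean 0.175), with 6 of 8 arrays correlating best with their own number in each. The planned block spanned all stages. A pair of narrower blocks, one for the spherical and tubular arrays within the fit of all arrays and one in a fit of those 8 arrays alone, was added after this check was seen.

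Alternatives were quantile normalization, subtraction of array medians, added constants of 1 and 64 on the linear scale, brighter probe sets only, array weights, trended and robust moderation, the arrays of the compared stages alone, each array left out in turn, other thresholds, and for lists fry, mean probe sets and members of 1 list only. Leaving out spherical replicates 3 and 4 together, and day 12 replicate 3 with day 14 replicate 1, was added after the principal components were seen. The correlation of successive changes was set beside 100 simulated data sets without change, drawn as random mixtures of the residual arrays. It was chosen after an independent draw per gene, which leaves out the correlation between genes. No 2 arrays held identical values, and differences between arrays of a stage had SDs of 0.237 to 0.467.

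The model was tested on simulated data made from the tubular and day 12 arrays with 23999 probe sets. Of 50 probe sets changed at each size, 36% were recovered at a log2 change of 0.5, 84% at 1, 98% at 2 and 100% at 4. Of 174 calls, which can include members of the glycolysis list, 6 were false. In tubular against spherical, which was left unchanged, 0 calls were made. Probe sets were drawn independently, without correlation between genes or between same-numbered arrays. These rates may therefore not hold for the real arrays.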

Results

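Gene expression was profiled across elongation of the pig conceptus, when the trophoblast lengthens from a sphere through a tube to a filament and then attaches to the uterine epithelium. The 4 stages were spherical (day 11), tubular (days 11 and 12), filamentous on day 12 and filamentous on day 14, each with 4 arrays from separate RNA pools. Median log2 signal per array lay between 7.05 and 7.21. Of 20 permutation tests of array medians, control ratios and spikes between compared stages 0 passed (adjusted p = 0.143 to 1). With 4 arrays per stage, a test at the smallest possible p passes this adjustment only if many others reach it too. The lack of a pass thus cannot show that the arrays were alike. The smallest unadjusted p that the permutations can give (0.0286) was reached by 4 tests. Among these, the 3' minus 5' log2 signal of the EF-1 alpha control was 0.07 ± 0.02 on day 14, -0.06 ± 0.03 on day 12 and 0.05 ± 0.04 in spherical conceptuses (SD, n = 4). The bioB spike was 8.20 ± 0.32 on day 12 and 8.86 ± 0.05 in spherical conceptuses. Of 23999 probe sets, 10698 (44.6%) differed among the stages by the moderated F test. The first principal component held 50.9% of the variance and the second 16.8%. On the first, the spherical and tubular arrays lay between -43.5 and -33.8, the day 12 arrays between 5.27 and 32.2 and the day 14 arrays between 59.0 and 71.9.

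**Figure D1:**
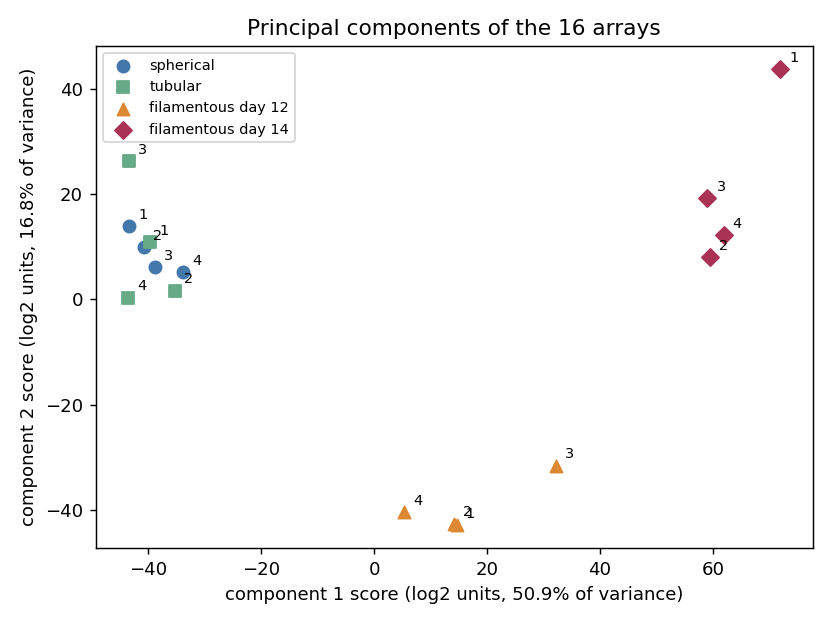
Principal components of the 16 arrays, each point 1 array, with colours for the 4 stages and component scores in log2 units on the axes. Spherical and tubular arrays overlap on the first component (50.9% of variance), and day 12 replicate 3 lies at 32.2, closer to the day 14 arrays than the other day 12 arrays.

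The onset of elongation was addressed by comparing tubular with spherical conceptuses. STAR, the carrier of cholesterol into mitochondria, had a log2 difference of 1.03 ± 0.44 (adjusted p = 0.473), and CYP11A1, the side-chain cleavage enzyme, one of 0.57 ± 0.23 (adjusted p = 0.45). Neither passed, nor did any other of the 21 panel genes (adjusted p = 0.282 to 0.997). In the fit of all arrays, 1 of 23999 probe sets was called. It was Ssc.13954.1.A1_at, which has no symbol here and is named after its values were seen. It rose from 8.05 ± 0.12 (SD, n = 4) to 8.79 ± 0.14 (log2 difference 0.74 ± 0.09, limma adjusted p = 0.00783). At an unadjusted p under 0.05 there were 2354 probe sets against 1200 expected by chance, and in 915 (3.81%, with 2.86% given by chance) the arrays of the stages did not overlap. Same-numbered arrays deviated together in these stages, and with those pairs as a block in the fit of all arrays 210 probe sets were called, 130 higher and 80 lower in tubular conceptuses. Each went in the same direction in 4 of 4 pairs, but the same pairs selected these probe sets, so this agreement is no further support. A block in the 8 arrays alone gave 65 calls, without the unnamed probe set, and the planned block over all stages gave 0. Without a block the count was 30 without tubular replicate 4, 4 without spherical replicate 1 and 0 without spherical replicate 2 or 3.

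In that blocked fit, FOXA1, a transcription factor of endoderm, was 5.96-fold higher in tubular conceptuses (adjusted p = 0.00012 with the block and 0.282 without). Its levels were 9.01 ± 1.46 in tubular and 6.44 ± 1.39 in spherical conceptuses (SD, n = 4). PPARG, a lipid-activated nuclear receptor, was 4.24-fold higher (adjusted p = 0.000675 with the block, 0.287 without). WEE1, a kinase that holds back mitosis, was 2.81-fold higher, the small GTPase RND3 2.46-fold and the Rho regulator ARHGAP29 2.42-fold. The growth factor HBEGF was 1.78-fold higher, the laminin chain LAMC1 1.42-fold, the tight junction gene CLDN4 1.72-fold and the protease gene PLAU 2.05-fold. The arrays of the stages overlapped for FOXA1, PPARG, HBEGF, LAMC1, CLDN4 and PLAU, so their calls rest on differences within pairs. Lower in tubular conceptuses were CLN8 (2.38-fold), the galactose kinase GALK1 (1.66-fold), the phospholipid enzyme LPCAT4 (1.62-fold) and GATA3, a trophoblast transcription factor (1.48-fold, adjusted p = 0.0396 with the block and 0.282 without). With the block in the 8 arrays alone FOXA1, PPARG, RND3, ARHGAP29, CLN8, GALK1 and LPCAT4 passed (adjusted p = 0.0226 to 0.0425). WEE1, HBEGF, LAMC1, CLDN4, PLAU and GATA3 did not (adjusted p = 0.072 to 0.121). Without a block RND3 passed without spherical replicate 1 (0.0354) and GALK1 without tubular replicate 4 (0.0498).

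Without a block, 0 members of any of the 22 lists passed over all probe sets by limma. Adjusted over the list alone, 1 prostaglandin gene was higher, 3 adhesion genes were higher and 1 lower, 1 trophoblast gene was higher and 3 lower, 1 hypoblast gene was higher and 1 mesoderm gene lower, with 0 in the other lists. By camera the cell cycle list was shifted down (median log2 difference -0.24, adjusted p = 6.27e-07, and adjusted p = 0.711 with an estimated correlation). The cytoskeleton list was shifted up (0.12, adjusted p = 0.00138, and adjusted p = 0.711 with an estimated correlation). The steroid list was shifted up (0.16, adjusted p = 0.0192, and adjusted p = 0.711 with an estimated correlation), as were the matrix protease list (0.17, adjusted p = 0.0267, and adjusted p = 0.711 with an estimated correlation) and the hypoblast list (0.13, adjusted p = 0.0336, and adjusted p = 0.725 with an estimated correlation). The steroid call ended without spherical replicate 4 (adjusted p = 0.079) or tubular replicate 3 (0.0519), the protease call without spherical replicate 3 (0.0585) or tubular replicate 1 (0.0598), and the hypoblast call without spherical replicate 1 (0.0613) or 3 (0.113) or tubular replicate 1 (0.149) or 3 (0.0843). Lists not called came near the threshold. The growth factor list (adjusted p = 0.0537, upward) passed under 10 settings (0.0214 to 0.0482), both scalings among them, the adhesion list (0.065, upward) passed under 6 (0.00368 to 0.0452), and oxidative phosphorylation (0.383, downward) passed with quantile normalization (0.0317). By fry, adjusted p was 0.118 to 0.262 for the 5 lists, and without spherical replicates 3 and 4 together it was 0.433 for the cytoskeleton list, 0.245 for steroids, 0.266 for proteases and 0.159 for hypoblast by camera.

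Rapid elongation was addressed by comparing day 12 filamentous with tubular conceptuses. MFSD4A, a membrane transporter family member, was 48.6-fold higher in filaments (95% interval 31.5 to 74.9, adjusted p = 1.26e-08). GJA1, a connexin of gap junctions, rose 16.7-fold, and CDO1, which oxidizes cysteine, rose 14.5-fold. TGFB3, a growth factor of the TGF-beta family, fell 23.1-fold (7.72 to 68.9, adjusted p = 0.000367). The TGFB3 fold was 36.7 without day 12 replicate 4, and that of CDO1 was 9.04 without tubular replicate 3. In all, 6296 probe sets (26.2%) changed, 2877 higher and 3419 lower, and 1105 of these changed at least 2-fold, 428 higher and 677 lower. The majority turned with quantile normalization, to 3334 higher and 2876 lower. With array medians subtracted 3052 were higher and 3127 lower. In 6738 probe sets (28.1%, with 2.86% given by chance) the arrays of the stages did not overlap.

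Other large rises were PLET1 (16.5-fold, adjusted p = 0.000183, and 10.6-fold without tubular replicate 3, its other probe set passing at a log2 difference of 2.35) and the hormone PTHLH (13.4-fold, adjusted p = 4.62e-05). Other large falls were MYLIP, a ubiquitin ligase (16.8-fold, adjusted p = 6e-07), the B-cell linker BLNK (14.0-fold), TRIM29 (13.9-fold) and ACSL6, which activates long-chain fatty acids (10.7-fold, adjusted p = 1.5e-06). In day 12 replicate 3, PTHLH stood at 11.1 against 9.08 to 9.34 in the other arrays of its stage, and ACSL6 at 7.84 against 9.48 to 9.76. Leaving that array out with day 14 replicate 1, a choice made after seeing the data, gave 5610 changed probe sets.

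Cell cycle and DNA replication genes rose together. Of 29 measured, 24 rose, 0 fell and 5 did not pass (26 rose adjusted over the list alone), and the list was shifted by camera (median log2 difference 0.81, adjusted p = 2.7e-12, and adjusted p = 0.711 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, rose 2.67-fold from 9.99 ± 0.26 to 11.4 ± 0.05 (SD, n = 4, limma adjusted p = 1.16e-06). The replication helicase subunit MCM4 rose 2.02-fold (1 of 2 probe sets passing) and the kinase CDK2 1.76-fold (2 of 3 passing, the third at a log2 difference of 0.08).

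Genes of steroid hormone synthesis fell, 10 of 19 with 0 rising and 9 not passing (11 fell adjusted over the list alone), and the list was shifted down (median -0.50, adjusted p = 0.0016, and adjusted p = 0.711 with an estimated correlation). POR, the electron donor of microsomal cytochromes P450, fell 6.53-fold (adjusted p = 6.94e-07). CYP17A1, which makes androgens, fell 4.86-fold from 13.1 ± 0.26 to 10.8 ± 1.18 (SD, n = 4, limma adjusted p = 0.00111), with day 12 replicate 3 at 9.07 and the others at 11.2 to 11.6, and fell 3.24-fold without that array. The aromatase CYP19A1 fell 2.07-fold (adjusted p = 0.0183), or by 0.66 on the log2 scale without day 12 replicate 3 (adjusted p = 0.0371), with 3 of 4 probe sets passing. HSD17B4 fell 2.52-fold and HSD17B1, which forms estradiol, 1.37-fold (adjusted p = 0.00708). STAR had a log2 difference of -0.69 ± 0.44 (adjusted p = 0.272), CYP11A1 had a fold of 1.42 (adjusted p = 0.124) with tubular replicate 4 at 12.5 against 13.0 to 13.1, and HSD3B1 had -0.23 ± 0.09 (adjusted p = 0.0732, but 0.0329 with array weights and 0.0403 without tubular replicate 4).

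Of 38 cytoskeletal genes, 3 rose and 13 fell (3 and 14 adjusted over the list alone), with 8 falling under quantile normalization. The list was shifted down (adjusted p = 0.03, and adjusted p = 0.725 with an estimated correlation). The actin-binding gene LIMA1 fell 6.52-fold, RDX 2.31-fold and VCL 1.71-fold (2 of 3 probe sets passing). Of 28 matrix proteases and inhibitors, 0 rose and 7 fell (0 and 8 adjusted over the list alone), with a downward shift (adjusted p = 0.037, and adjusted p = 0.713 with an estimated correlation). PLAU, the urokinase gene, fell 5.41-fold and the cathepsin CTSD 2.02-fold, with day 12 replicate 3 at 10.7 for CTSD against 10.2 to 10.3. Of 32 oxidative phosphorylation genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone, with 3 falling under quantile normalization and 5 with medians subtracted), also with a downward shift (median -0.15, adjusted p = 0.037, and adjusted p = 0.713 with an estimated correlation), among them the complex I subunits NDUFV1 (1.55-fold) and NDUFB8 (1.33-fold, with day 12 replicate 4 at 12.0 against 11.9 in the others). The cytoskeleton call ended with quantile normalization (adjusted p = 0.0761), and the protease call without tubular replicate 1 (0.0735) or 2 (0.0567) or with brighter probe sets only (0.0699). The oxidative phosphorylation call ended without day 12 replicate 3 (0.0704) or 4 (0.0512) or tubular replicate 4 (0.146), and under 7 other settings including quantile normalization (0.52).

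PTGS2, the inducible prostaglandin synthase, rose 8.62-fold from 10.0 ± 2.09 to 13.1 ± 0.11 (SD, n = 4, limma adjusted p = 0.00663). The fold was 14.8 without tubular replicate 2 and 5.11 without tubular replicate 3. The prostaglandin E synthase PTGES fell 2.18-fold, with day 12 replicate 3 at 11.4 against 12.1 to 12.2. In the prostaglandin list 1 of 11 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.815). IFNG, the interferon gamma gene, rose from 11.8 ± 0.61 to 14.0 ± 0.14 (SD, n = 4, limma adjusted p = 5.21e-06). That level is near the largest value on the arrays (14.5), so no fold is given. In the interferon list 1 of 27 rose and 3 fell (1 and 2 adjusted over the list alone, adjusted p = 0.81), and ISG15 had a log2 difference of -0.04 ± 0.10 (adjusted p = 0.848). In the interleukin-1 list 2 of 16 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.901). The cytokine LIF rose 2.58-fold and the NF-kappa B inhibitor NFKBIA fell 1.64-fold (adjusted p = 0.0182), a call lost without tubular replicate 1 (0.0636) or 3 (0.0561). IL1B lay near the top of the scale in both stages, at 14.3 ± 0.07 and 14.2 ± 0.08 (SD, n = 4, limma adjusted p = 0.963).

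Among growth factors and receptors 4 of 31 rose and 6 fell (4 and 7 adjusted over the list alone, adjusted p = 0.719). VEGFA, the vascular growth factor, rose 4.27-fold (2 of 4 probe sets passing), EGFR fell 2.46-fold (day 12 replicate 3 at 9.43, the others at 9.14 to 9.19) and IGF2R fell 2.14-fold. Of 39 oxidant, heat shock and hypoxia genes 12 rose and 6 fell (12 and 7 adjusted over the list alone, adjusted p = 0.205, and 0.00865 by fry). The chaperone HSPB1 rose 3.49-fold, the glutathione reductase GSR 2.96-fold (2 of 3 probe sets passing) and the heme oxygenase HMOX1 2.61-fold, with tubular replicate 4 at 10.7 for HMOX1 against 9.76 to 9.91, and catalase (CAT) fell 1.58-fold. Of 20 glycolysis genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.81), with LDHB 1.45-fold higher and the glycogen synthase GYS1 2.09-fold lower (3 of 3 probe sets passing, at log2 differences of -1.06 to -0.39). Of 18 cholesterol genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.18). Without tubular replicate 1 the list passed upward (adjusted p = 0.0104), its mean there being 10.0 against 9.20 to 9.34 in the other tubular arrays. Its members FDFT1 (2.09-fold) and MSMO1 (2.30-fold, 2 of 3 probe sets passing and the third at a log2 difference of -0.42) of the synthesis pathway were higher and the lysosomal exporter NPC1 was 1.54-fold lower. Of 29 adhesion genes 0 rose and 8 fell (0 and 8 adjusted over the list alone, adjusted p = 0.163, and 0.0105 by fry, with 1 rising and 5 falling under quantile normalization), among them the desmosomal DSP (2.76-fold, its other probe set passing at a log2 difference of -0.94) and the cadherin CDH1 (1.39-fold, 1 of 2 passing), and SPP1 had a log2 difference of -0.02 ± 0.33 (adjusted p = 0.976). SPP1 was dim in the tubular and day 12 arrays (6.24 and 6.22), which limits what its lack of a call can show. Of 51 ribosomal protein genes 0 rose and 1, RPL37, fell (1.84-fold, and 0 and 0 adjusted over the list alone, adjusted p = 0.163). That list passed upward with quantile normalization (0.0419) and with trended and robust moderation (0.0262).

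Among trophoblast markers 5 of 17 rose and 7 fell (5 and 8 adjusted over the list alone, adjusted p = 0.815, and 0.0313 by fry). ETS2 fell 5.16-fold, DLX5 rose 3.17-fold and GATA3 rose 1.75-fold (3 of 4 probe sets passing). KRT8 was lower (adjusted p = 0.0493), a call lost without any 1 of the 8 arrays (0.0553 to 0.13) and with either scaling (0.101 with medians subtracted, 0.0835 quantile). The other KRT8 probe set, which is dimmer, passed and fell by 0.71 on the log2 scale. KRT18 did not pass (adjusted p = 0.257). The brightest KRT8 probe set (14.2 and 14.0) and KRT18 (14.4 and 14.2) lay near the largest value on the arrays (14.5), so no sizes are given for them. Of 16 mesoderm markers 3 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.466), with HAND1 4.43-fold and POSTN 2.05-fold higher (1 of 2 POSTN probe sets passing). HAND1 counted as mesoderm by its list, and which cells of the pools express it was not tested. Of 4 epiblast genes measured 2 rose (2 and 0 adjusted over the list alone, adjusted p = 0.363, and 0.0284 by fry), ZFP42 by 1.59-fold and DNMT3B by 1.60-fold, and POU5F1 had a log2 difference of -0.46 ± 0.22 (adjusted p = 0.144). Of 26 hypoblast markers 1 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.905, with 1 falling under quantile normalization). AMN fell 2.32-fold and HNF4A rose 1.38-fold (adjusted p = 0.0177, 1 of 2 probe sets passing), a call lost without day 12 replicate 3 (0.0616) or tubular replicate 4 (0.0554), while GATA4 (0.16 ± 0.14, adjusted p = 0.47, tubular replicate 4 at 7.44 against 7.96 to 8.06), RBP4 (0.50 ± 0.32, adjusted p = 0.277) and the mesoderm marker VIM (0.52 ± 0.31, adjusted p = 0.252) did not pass. In the blood list 1 of 16 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.823), with the globin gene HBB 1.69-fold higher (adjusted p = 0.0111). In the leukocyte list 1 of 24 rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.945), with AIF1 6.24-fold higher and PTPRC at -0.15 ± 0.12 (adjusted p = 0.407). In the uterine list 1 of 19 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.671), with PLET1 higher as above, DPP4 3.99-fold lower and ACP5 at 0.06 ± 0.22 (adjusted p = 0.867).

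**Figure D2:**
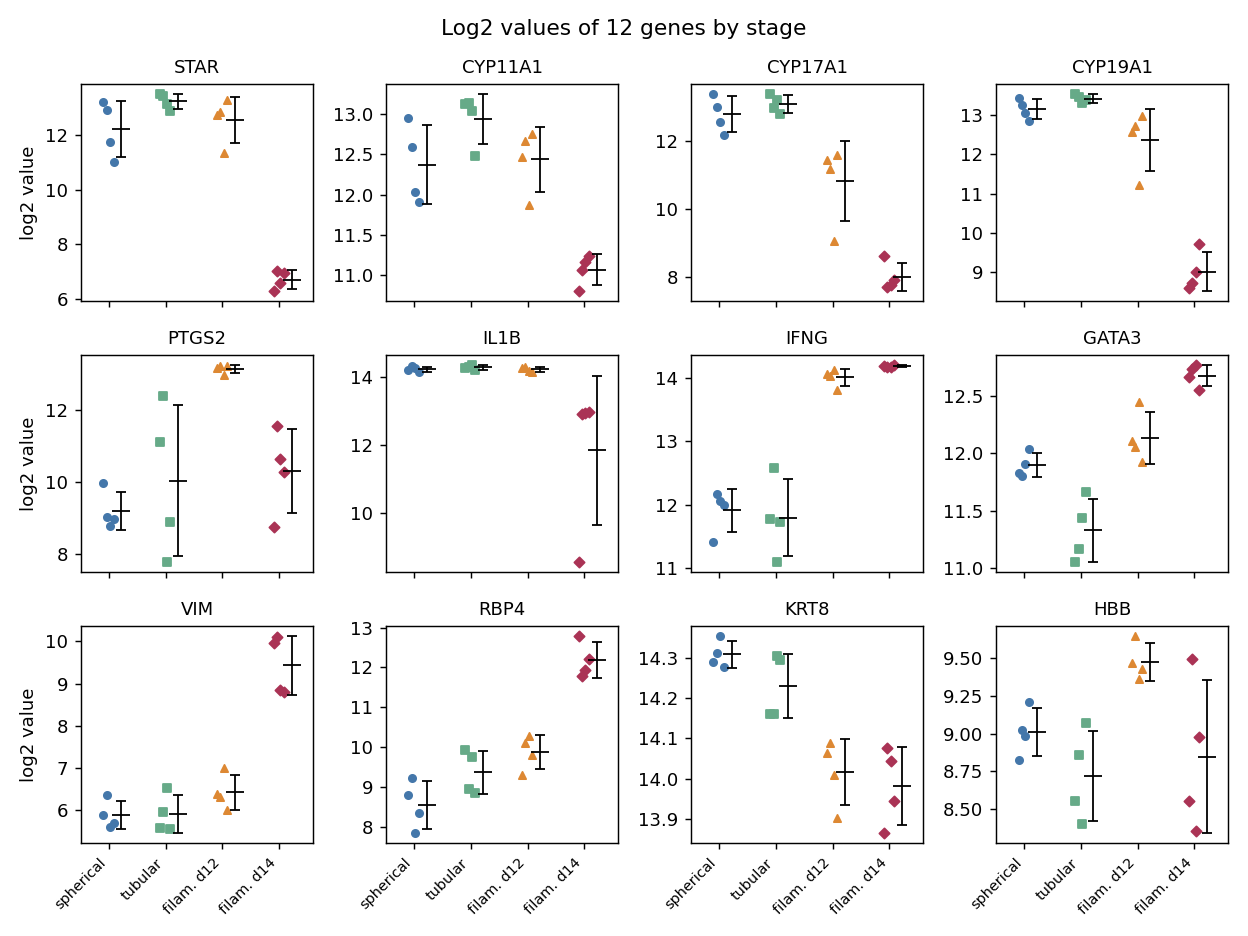
Log2 signal of selected genes in each of the 16 arrays by stage, with points for arrays and bars for the mean and SD of 4 arrays. STAR lies at 12.2 to 13.3 on average in the earlier stages and at 6.71 on day 14, and IFNG at 11.8 to 11.9 in spherical and tubular conceptuses and at 14.0 and 14.2 in filaments.

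The period of attachment was addressed by comparing day 14 with day 12 filaments. STAR fell 57.6-fold, from 12.6 ± 0.84 to 6.71 ± 0.35 (SD, n = 4, limma adjusted p = 7.26e-07), and CYP19A1 fell 10.1-fold (3 of 4 probe sets passing, the fourth at a log2 difference of 0.10). The chemokine CXCL14 rose 21.0-fold (95% interval 11.1 to 39.7, adjusted p = 8.95e-06), the lysosomal nuclease DNASE2 rose 12.8-fold, and VIM, an intermediate filament of mesenchymal cells, rose 8.01-fold. In all, 6478 probe sets (27.0%) changed, 3935 higher and 2543 lower, and 1048 changed at least 2-fold, 700 higher and 348 lower. The higher share of 60.7% became 42.0% when array medians were subtracted and 49.2% with quantile normalization. Array medians were 7.18 ± 0.03 on day 14 and 7.07 ± 0.02 on day 12 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.143), and subtracting them moved the median of all differences by -0.11, to which changes in this comparison are relative. The arrays did not overlap in 6684 probe sets (27.9%, with 2.86% given by chance).

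Other large rises were IFN-DELTA-1, an interferon gene of the trophoblast (12.8-fold, adjusted p = 2.38e-05, and 8.46-fold without day 14 replicate 1), and the enolase ENO3 (10.9-fold, adjusted p = 4.93e-07). Other large falls were the bile acid transporter SLC10A1 (19.3-fold, and 29.3-fold without day 12 replicate 3), ACSL6 (14.9-fold, with 1 of 2 probe sets passing and the other at a log2 difference of -0.63) and the lysophosphatidic acid receptor LPAR3 (10.1-fold, and 6.28-fold without day 14 replicate 1). ACSL6 stood at 7.84 in day 12 replicate 3 against 9.48 to 9.76 in the others, and leaving out that array with day 14 replicate 1, a choice made after seeing the data, gave 5090 changed probe sets.

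Steroid synthesis genes fell, 9 of 19 with 2 rising and 8 not passing (10 and 2 adjusted over the list alone), and the list was shifted down (median -0.53, adjusted p = 0.000837, and adjusted p = 0.711 with an estimated correlation). CYP17A1 fell 7.10-fold (10.7-fold without day 12 replicate 3), HSD17B1 2.65-fold, CYP11A1 2.57-fold and the electron carrier FDX1 2.46-fold, where day 12 replicate 3 stood at 12.6 against 13.3 to 13.4 and day 14 replicate 4 at 12.1 against 11.7. NR5A2, a nuclear receptor, rose in all 5 of its probe sets (log2 differences 0.46 to 2.42, with 1.38-fold in the brightest). HSD3B1 had a log2 difference of 0.18 ± 0.09 (adjusted p = 0.157). Of 18 cholesterol genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), with a downward shift (adjusted p = 0.037, and adjusted p = 0.752 with an estimated correlation). INSIG1, a feedback regulator of sterol synthesis, fell by 1.85 on the log2 scale (its other probe set passing at -0.64) and NPC1 fell 1.95-fold, with day 12 replicate 3 at 9.61 for NPC1 against 9.51 in the others. The cholesterol call ended without day 12 replicate 3 (adjusted p = 0.159) or day 14 replicate 3 (0.0558) or 4 (0.0876), with both scalings (0.0924 with medians subtracted, 0.0741 quantile), and under other settings up to 0.138.

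Hypoblast and extraembryonic endoderm markers rose, 12 of 26 with 0 falling (12 and 1 adjusted over the list alone), and the list was shifted up (median 0.40, adjusted p = 0.00738, and adjusted p = 0.711 with an estimated correlation). Transferrin (TF) rose 6.52-fold (its other probe set passing at a log2 difference of 0.55), the thyroxine carrier TTR 5.37-fold, the retinol carrier RBP4 4.97-fold from 9.87 ± 0.42 to 12.2 ± 0.45 (SD, n = 4, limma adjusted p = 0.000115, the other probe set passing at a log2 difference of 0.51) and HNF4A 1.69-fold (the other passing at 0.44), while GATA4 had 0.27 ± 0.14 (adjusted p = 0.192). Mesoderm markers rose in 5 of 16 with 0 falling (6 and 0 adjusted over the list alone) and were shifted up (median 0.31, adjusted p = 0.0336, and adjusted p = 0.711 with an estimated correlation), with BMP4 3.27-fold and DCN 3.58-fold (1 of 2 probe sets passing, the other at a log2 difference of 0.19) higher beside VIM. LUM rose from a dim 2.33 ± 0.53 to 5.69 ± 1.65 (SD, n = 4, limma adjusted p = 0.000599, and 0.000693 without day 14 replicate 1), and no size is given at that level. Markers of other cells moved too. The leukocyte list had 2 of 24 higher and 0 lower (2 and 0 adjusted over the list alone, adjusted p = 0.363), with ITGB2 5.73-fold (3.46-fold without day 14 replicate 1) and S100A8 1.64-fold higher and PTPRC at 0.26 ± 0.12 (adjusted p = 0.126, day 14 replicate 4 at 5.59 against 6.01 to 6.07, and adjusted p = 0.0196, higher, without that array). HBB fell 1.55-fold (adjusted p = 0.0286), the only passing member of 16 in the blood list (0 and 0 adjusted over the list alone, adjusted p = 0.754), a call lost without day 12 replicate 1, 2 or 4 or day 14 replicate 1 or 3 (0.0503 to 0.1, at log2 differences of -0.47 to -0.65). The uterine list had 3 of 19 higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.213, and 0.00865 by fry). IHH rose 1.61-fold (its other probe set passing at a log2 difference of 0.30), ACP5 1.63-fold (adjusted p = 0.024, lost without day 12 replicate 1 or day 14 replicate 1 or 4 at 0.0578 to 0.0868, and with either scaling at 0.0517 and 0.0556) and MUC4 4.39-fold (adjusted p = 0.0242, lost without day 12 replicate 1, 3 or 4 or day 14 replicate 1 or 4 at 0.0514 to 0.0882, with day 12 replicate 2 at 5.19 against 3.55 to 3.83, and 7.64-fold without day 14 replicate 2). The hypoblast call ended with brighter probe sets only (adjusted p = 0.0678), and the mesoderm call there (0.369), with members of 1 list only (0.0837) and without day 12 replicate 2 (0.0587) or day 14 replicate 2 (0.0547).

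Cell cycle genes fell, 10 of 29 with 1 rising (10 and 1 adjusted over the list alone), and the list was shifted down (median -0.31, adjusted p = 0.000314, and adjusted p = 0.725 with an estimated correlation). The cyclin CCNA2 fell 2.79-fold, MCM4 1.96-fold (1 of 2 probe sets passing) and PCNA 1.79-fold, and the phosphatase CDC25C rose 1.61-fold. By fry this list did not pass (adjusted p = 0.0698). Glucose uptake and glycolysis genes rose, 9 of 20 with 1 falling (13 and 1 adjusted over the list alone), and were shifted up (median 0.35, adjusted p = 0.0116, and adjusted p = 0.711 with an estimated correlation). GAPDH rose 1.46-fold (4 of 5 probe sets passing), the phosphofructokinase PFKL 1.78-fold and the hexokinase HK1 1.65-fold, and the glucose transporter SLC2A1 fell 1.69-fold.

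PTGS2 fell 7.15-fold (adjusted p = 0.0114, and 0.0615 without day 12 replicate 3 and day 14 replicate 1), PTGES fell 3.81-fold and the constitutive synthase PTGS1 rose 2.28-fold (its other probe set passing at a log2 difference of 0.65), with 2 of 11 prostaglandin genes higher and 3 lower (2 and 3 adjusted over the list alone, adjusted p = 0.754). IL1B, which in pig has near-identical copies, fell from 14.2 ± 0.08 to 11.8 ± 2.19 (SD, n = 4, limma adjusted p = 0.0165, and 0.074 in the 8 arrays of these stages alone). Its day 12 level lay near the largest value on the arrays (14.5), so no fold is given. Day 14 replicate 1 stood at 8.56 and the others at 12.9 to 13.0. Without that array IL1B still passed (adjusted p = 1.8e-07), with a difference of at most -1.28 on the log2 scale, as a level near the top can be understated. IL6 fell 1.46-fold, and in the interleukin-1 list 0 of 16 rose and 2 fell (0 and 2 adjusted over the list alone, adjusted p = 0.582). In the interferon list 4 of 27 rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.18, but 0.00151 by fry and 0.0251 with mean probe sets), with TAP1 3.61-fold (1 of 3 probe sets passing, log2 differences 0.06 to 1.85), IFNGR1 1.78-fold and MX1 1.33-fold higher. IFNG did not pass (adjusted p = 0.612). At 14.0 and 14.2 it lay near the largest value on the arrays, where a further rise might not be seen. ISG15 had 0.19 ± 0.10 (adjusted p = 0.186). Of 31 growth factors and receptors 14 rose and 4 fell (15 and 4 adjusted over the list alone, adjusted p = 0.0684). The list passed upward with medians subtracted (0.0328), by fry (0.000936) and without day 14 replicate 2 (0.0423). Among its members IGFBP5 was 7.28-fold, FGFR2 2.91-fold and EGFR 2.47-fold higher (the other EGFR probe set passing at a log2 difference of 0.57) and VEGFA was 2.12-fold lower (2 of 4 passing).

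Of 38 cytoskeletal genes 6 rose and 10 fell (7 and 11 adjusted over the list alone, adjusted p = 0.358), with LIMA1 3.20-fold and MSN 1.98-fold lower (the other MSN probe set passing at a log2 difference of -1.81) and the myosin MYH9 1.67-fold higher (1 of 2 passing). Of 28 matrix proteases and inhibitors 8 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 0.234, with 5 rising with medians subtracted), with ADAMTS1 2.26-fold (its other probe set passing at a log2 difference of 0.34) and the gelatinase MMP2 2.92-fold higher and CTSZ 3.61-fold lower. Of 29 adhesion genes 3 rose and 1 fell (3 and 0 adjusted over the list alone, adjusted p = 0.582, and 3 and 3 with array medians subtracted), with the integrins ITGB1 (1.33-fold) and ITGB3 (1.44-fold) higher and the junction gene OCLN 1.23-fold lower (adjusted p = 0.0373, lost without day 12 replicate 1, 2 or 4 or day 14 replicate 1 or 2 at 0.0582 to 0.12, although all 3 OCLN probe sets passed, at log2 differences of -0.88 to -0.30), and SPP1 at 0.03 ± 0.33 (adjusted p = 0.966). Of 39 oxidant, heat shock and hypoxia genes 8 rose and 10 fell (11 and 11 adjusted over the list alone, adjusted p = 0.466), with HMOX1 7.06-fold and CAT 1.63-fold lower and GPX1 2.15-fold higher. Among trophoblast markers 5 of 17 rose and 3 fell (5 and 4 adjusted over the list alone, adjusted p = 0.987), with ID2 2.83-fold (day 12 replicate 3 at 7.06 against 6.56 to 6.63), ELF3 2.08-fold (1 of 2 probe sets passing) and GATA3 1.46-fold (2 of 4 passing) higher. KRT8 (adjusted p = 0.79) and KRT18 (adjusted p = 0.077) did not pass. KRT18 passed, lower, with medians subtracted (0.0247), with trended and robust moderation (0.0437) and without day 14 replicate 2 (0.0354). Both lay at day 12 levels near the largest value, where a change can be understated. Of 4 epiblast genes 1 rose and 1 fell (2 and 2 adjusted over the list alone, adjusted p = 0.706, and 0 and 2 with medians subtracted). POU5F1 rose 1.55-fold (adjusted p = 0.041), a call lost with medians subtracted (0.0775), with quantile normalization (0.0733) and without any day 12 array or day 14 replicate 2 or 3 (0.0532 to 0.13), and ZFP42 fell 1.63-fold. In oxidative phosphorylation 1 of 32, NDUFS7, was higher (1.22-fold, adjusted p = 0.0444) and 0 fell (0 and 0 adjusted over the list alone, adjusted p = 0.668), but with medians subtracted 0 rose and 2 fell and NDUFS7 did not pass (0.224), nor did it without any array but day 14 replicate 2 (0.0583 to 0.134). Of 51 ribosomal protein genes 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, adjusted p = 0.329), and with medians subtracted 3 fell and the list passed downward (adjusted p = 0.00407). In the tubular arrays the mean of this list was 13.2, against a largest value of 14.5, and at high levels a change can be understated.

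**Figure D3:**
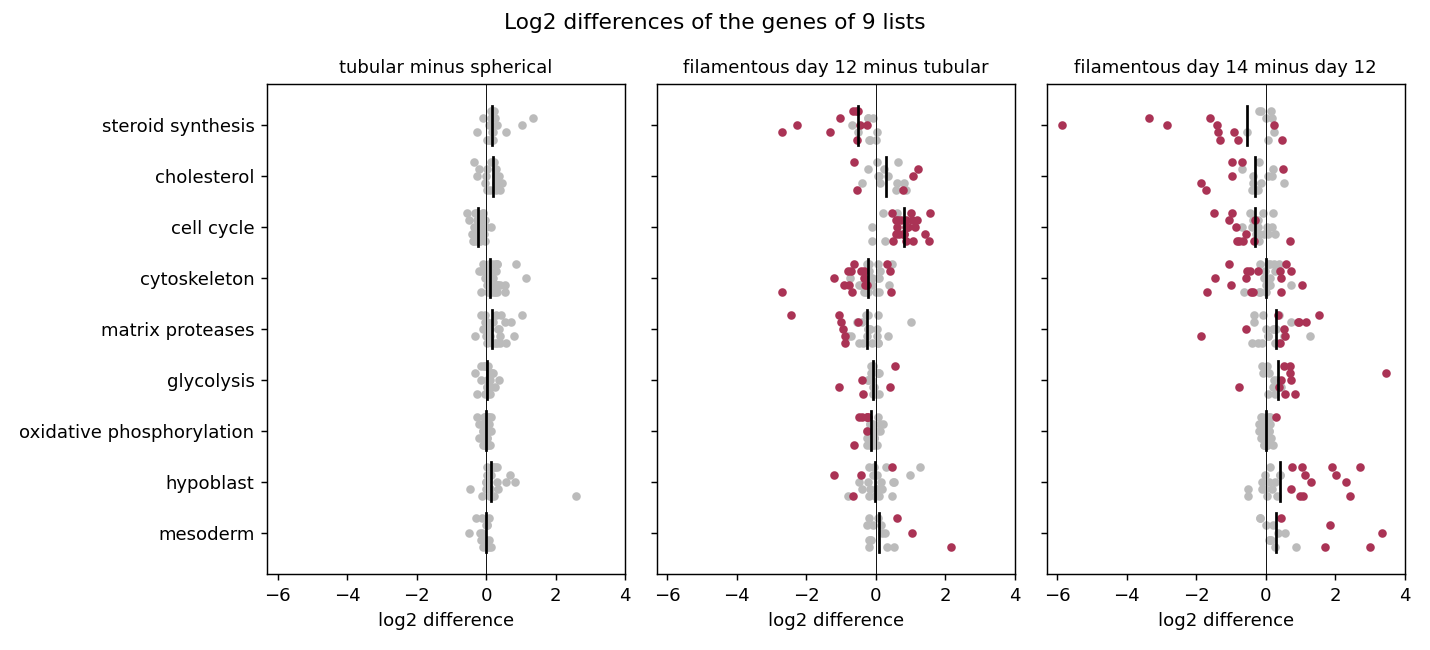
Log2 differences of the members of selected gene lists in the successive comparisons, with each point 1 gene, red for an adjusted p under 0.05, grey for the rest, and a black line at the list median. The cell cycle median is -0.24, 0.81 and -0.31 in turn and the steroid median 0.16, -0.50 and -0.53, and on day 14 the oxidative phosphorylation calls turn from 1 higher and 0 lower to 0 higher and 2 lower with array medians subtracted.

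The whole of elongation was addressed by comparing day 12 filaments with spherical conceptuses. MFSD4A was 53.8-fold higher (95% interval 34.9 to 82.9, adjusted p = 6.08e-09), CDO1 26.4-fold and GJA1 21.9-fold. BLNK fell 29.6-fold, TRIM29 20.0-fold and ABCG2, a drug and sterol-conjugate exporter, 10.3-fold (adjusted p = 3.97e-09, its other probe set passing at a log2 difference of -0.80). In all, 5621 probe sets (23.4%) changed, 2691 higher and 2930 lower, and 1072 changed at least 2-fold, 471 higher and 601 lower. The majority turned with quantile normalization, to 2925 higher and 2745 lower. With array medians subtracted 2680 were higher and 2890 lower. The arrays did not overlap in 6882 probe sets (28.7%, with 2.86% given by chance).

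CYP26A1, which breaks down retinoic acid, rose 9.55-fold, with day 12 replicate 3 at 11.5 against 9.32 to 9.51. Of 29 cell cycle genes 18 rose and 0 fell (19 and 1 adjusted over the list alone), with TOP2A 2.10-fold higher and an upward shift (adjusted p = 1.45e-07, and adjusted p = 0.711 with an estimated correlation). Of 19 steroid genes 1 rose and 8 fell (1 and 9 adjusted over the list alone), with POR 5.67-fold and CYP17A1 3.92-fold lower (2.61-fold without day 12 replicate 3) and a downward shift (adjusted p = 0.0336, and adjusted p = 0.711 with an estimated correlation). Of 32 oxidative phosphorylation genes 0 rose and 9 fell (0 and 9 adjusted over the list alone, with 4 falling under quantile normalization and 6 with medians subtracted), with NDUFV1 1.43-fold lower and a downward shift (adjusted p = 0.00629, and adjusted p = 0.711 with an estimated correlation). PTGS2 rose 15.4-fold (adjusted p = 0.00139) and IFNG was higher (adjusted p = 8.03e-06, with its day 12 level near the top of the scale as above). KRT8 was lower at a level near the top of the scale (adjusted p = 0.0109), and this call was lost without spherical replicates 3 and 4 (0.061). Its other probe set passed and fell by 0.76 on the log2 scale. HSD17B1 fell 1.29-fold (adjusted p = 0.024), lost without day 12 replicate 3 (0.0838) or spherical replicate 1 (0.0635), 2 (0.0591) or 3 (0.0519), and HSD3B1 fell 1.24-fold (adjusted p = 0.0177, 1 of 2 probe sets passing), lost without day 12 replicate 1 (0.055) or spherical replicate 4 (0.0501). PPARG rose 4.20-fold (adjusted p = 0.0111) and RBP4 2.50-fold (adjusted p = 0.0067, 1 of 2 probe sets passing), and neither passed without spherical replicates 3 and 4 (0.18 and 0.107). The steroid call ended without day 12 replicate 3 (adjusted p = 0.0704) or spherical replicate 1 (0.0807), in the 8 arrays alone (0.0624) and with the mean of a gene's probe sets (0.0558). Of the lists not called, cholesterol (6 of 18 higher and 2 lower) passed under 3 settings (adjusted p = 0.0132 to 0.0497, median log2 differences 0.44 to 0.48). By fry alone the trophoblast (0.000848), oxidant (0.00308), epiblast (0.00349) and retinoid (0.00896) lists passed. Leaving out spherical replicates 3 and 4 gave 4500 changed probe sets, and leaving out day 12 replicate 3 with day 14 replicate 1 gave 5152, both chosen after seeing the data.

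Changes in successive transitions were also set against each other over all probe sets, which are not independent replicates. Between the first and second transitions the correlation of log2 differences was -0.22, where simulated data without change gave -0.49 (-0.94 to 0.30), because the middle stage enters both with opposite sign. The covariance was -0.0256 against a simulated -0.0165. With the middle stage split the correlation was -0.0779. Between the transitions from tubular to day 12 and from day 12 to day 14 the correlation was -0.04 against a simulated -0.47 (-0.89 to 0.39), the covariance -0.0108 against -0.0145, and the split correlation 6e-04. For both pairs the observed covariance lay within the range of the simulations.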

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

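The tests of the spread between arrays, of blood, leukocytes and trophoblast share and of day 12 arrays shared by both comparisons were chosen only after the result was seen, as were the narrower blocks and the fits without pairs of arrays. The exchange of spherical replicate 1 with tubular replicate 4 was picked from the splits below, and its bounds were set before its correlations were seen. In 421 groups of 4 arrays, the gap of 1 array to the nearest other passed Dixon's 95% critical value in 23, where chance gives about 21. Of the 23, 10 were day 12 replicate 3 and 3 were tubular replicate 4.

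In day 12 replicate 3, CYP17A1 stood at 9.07 (others 11.2 to 11.6), ACSL6 at 7.84 (9.48 to 9.76), PTGES at 11.4 (12.1 to 12.2) and FDX1 at 12.6 (13.3 to 13.4), all below the rest. PTHLH stood at 11.1 (9.08 to 9.34), CYP26A1 at 11.5 (9.32 to 9.51), CTSD at 10.7 (10.2 to 10.3), EGFR at 9.43 (9.14 to 9.19), NPC1 at 9.61 (9.51) and ID2 at 7.06 (6.56 to 6.63), all above. IL1B stood at 8.56 in day 14 replicate 1 (12.9 to 13.0), FDX1 at 12.1 (11.7) and PTPRC at 5.59 (6.01 to 6.07) in day 14 replicate 4. In tubular replicate 4, CYP11A1 stood at 12.5 (13.0 to 13.1), HMOX1 at 10.7 (9.76 to 9.91) and GATA4 at 7.44 (7.96 to 8.06). NDUFB8 stood at 12.0 (11.9) and NDUFS7 at 10.4 (10.7) in day 12 replicate 4, and MUC4 at 5.19 (3.55 to 3.83) in day 12 replicate 2. The mean of the cholesterol list was 10.0 in tubular replicate 1 (9.20 to 9.34), and in tubular replicate 3 the glycolysis mean was 9.67 (9.50 to 9.53) and the ribosomal mean 13.2 (13.2). The bioB spike control read 7.72 in day 12 replicate 1 (8.33 to 8.39).

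Counts of changed probe sets were set against other splits of the same arrays. For day 12 filamentous against tubular 1 of 35 splits, the real one, gave as many (6296, highest other 1), for day 14 against day 12 it was 1 (6478, highest other 5) and for day 12 against spherical 1 (5621, highest other 1). For the F test 1 of 100 regroupings gave as many (10698, highest other 1518). For each of these counts the real grouping stood alone, which is the smallest share that such regroupings can give. That share is under 0.05 but was not adjusted over the comparisons, so chance is made unlikely and is not excluded. For tubular against spherical 5 of the 35 splits gave at least 1 call (highest other 242), so chance was not excluded for that count. Among the 8 splits that part all pairs the real one gave 1 and the highest other 0, while the other 27 splits, which leave pairs together, reached 242. Called lists numbered 5, 5, 6 and 3 in the comparisons in the order of the report, and 3, 2, 5 and 16 of 35 splits gave as many (highest others 7, 5, 6 and 5). Of these, chance was not excluded for any, at shares of 0.05 or more. With the pairs as a block, 1 of the 8 exchanges within pairs gave 210 and the highest other 2, and 8 exchanges are too few for a share under 0.05.

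Few probe sets changed from spherical to tubular conceptuses. The typical spread between these arrays was not larger, as their median residual SD was 0.984 of that of the filamentous arrays. Being a median over all probe sets, this ratio cannot exclude a larger spread in part of the genes. Shared variation of same-numbered arrays may account for part of the low count, as the added block in the fit of all arrays gave 210 calls in place of 1. The added block in the 8 arrays alone gave 65, and the planned block over all stages gave 0. Spherical replicates 3 and 4 being unlike 1 and 2 was seen in the principal components. The fit without replicates 3 and 4 gave 0 calls, but fewer arrays also lower a count, so that fit cannot decide whether this unlikeness plays a part. The split with 242 calls exchanges spherical replicate 1 and tubular replicate 4 and points to a structure of the samples. By median Spearman correlation, both lay nearer the other stage than their own (0.9902 against 0.9848, and 0.9878 against 0.9838). So did spherical replicate 2 (0.9882 against 0.9873) and tubular replicate 3 (0.9826 against 0.9815). But after that exchange the mean correlation of pairs was 0.136 with 2 of 4 over 0.1, against 0.248 and 4 as labelled. An exchange and true labels cannot be told apart from these values, and a biological likeness of the stages stays untested.

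On day 14, 12 of 26 hypoblast and 5 of 16 mesoderm markers were higher (camera adjusted p = 0.00738 and 0.0336, and 0.711 for both with an estimated correlation). Blood in the pools would raise HBB, which instead had a log2 difference of -0.632 (adjusted p = 0.0286), and -0.468 to -0.649 without 1 of the 5 arrays whose absence ends the call (adjusted p = 0.0503 to 0.1). Maternal leukocytes stay open. They would raise their own markers as much, and the median of 5 leukocyte markers lay -0.552 from that of 26 hypoblast and mesoderm markers (permutation p = 0.498), too few genes to decide. A lower trophoblast share also stays open. The hypoblast and mesoderm markers differed from genes of the epiblast, blood, leukocyte and uterine lists by 0.511 (permutation p = 0.0755, medians 0.749 over 26 genes and 0.238 over 18). PLET1 and IHH counted as uterine and HAND1 as mesoderm by their lists. Which cells of the pools express these genes was not tested, which limits this comparison. The stages differ in day by design, and a biological difference between them stays open and untested.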

How the results depend on the processing

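Lists were shifted by limma's camera in 19 of 88 tests with a preset correlation, in 0 with an estimated one and in 16 to 21 without each array in turn. The cause was not tested. Of 150 called gene results, 134 passed under every alternative fit run for them, 16 were lost under some and 0 reversed. The other thresholds were not applied to single genes, and the fit of brighter probe sets only held 124 of the 150. The rule favours large changes and small p, and the genes were picked after their values were seen, so the share of 134 does not carry over to all calls. Of all 6296 calls for day 12 filamentous against tubular, 4847 were still called without tubular replicate 3. Of 19 called lists, 0 passed under every alternative. Of 69 list tests not called, 20 passed under some alternative, 11 of them by fry alone, which does not compare a list with other genes.

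For tubular against spherical the count of 1 was 0 in the 8 arrays alone, 0 with the planned replicate block, 210 and 65 with the added narrower blocks, 0 without spherical replicates 3 and 4, 0 at 2-fold or more and 83 at an unadjusted p under 0.001. Without each array in turn it was 0 to 30, with 30 without tubular replicate 4, 4 without spherical replicate 1 and 0 without spherical replicate 2 or 3. For day 12 filamentous against tubular the count of 6296 was 1105 at 2-fold or more, 3324 at an unadjusted p under 0.001, 3718 at an adjusted p under 0.01 and 4944 to 6316 without each array. For day 14 against day 12 the count of 6478 was 1048, 3300, 3734 and 5054 to 6583 in the same order, and for day 12 against spherical the count of 5621 was 1072, 2993, 3225 and 4449 to 5193. Stricter thresholds lower a count by construction. The F test count was 9363 to 10869 without each array. In the comparisons after the first, same-numbered arrays did not deviate together, and the planned replicate block gave 6926, 7134 and 6192 calls, and of the called lists it ended the cholesterol call alone (adjusted p = 0.0581). With the middle stage split the correlations of successive changes moved from -0.22 to -0.0779 and from -0.04 to 6e-04, as the split removes the shared arrays. Signal over background is not given per probe set, and it limits the dim genes.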

Other observations

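Genes of retinoid, folate, iron and amino acid handling, a list that did not pass as a whole by camera, had members with large changes. From tubular to day 12 filamentous conceptuses 7 of 24 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.169, and 0.0455 by fry). The spermidine synthase SRM rose 2.83-fold, the arginine transporter SLC7A1 2.53-fold and the transferrin receptor TFRC 1.54-fold, and SAT1, which acetylates polyamines, fell 1.68-fold. From day 12 to day 14, 9 of 24 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.139, and 0.000869 by fry). SAT1 rose 2.21-fold, TF 6.52-fold and RBP4 4.97-fold, and the amino acid transporter chain SLC3A2 fell 1.57-fold. TF and RBP4 are also in the hypoblast list.

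Probe sets that rose to day 12 and fell by day 14 numbered 962, against 304.9 for independent lists (ratio 3.16), those that fell and then rose 837 against 560.6, those that fell and fell again 421 against 362.3 and those that rose and rose again 324 against 471.7. The day 12 arrays enter both comparisons with opposite sign, which by chance raises the overlaps of opposite direction. With those arrays split, the mean overlap of rise and fall was 326.7 against 108.6, and the lowest ratio over 6 splits was 2.206 (highest 4.67), so sharing alone was excluded as the whole source. After quantile normalization the lowest ratio was 1.98 (highest 3.99), just under the bound of 2 set beforehand, and normalization of the day 12 arrays therefore stays open. With the arrays split, the other overlaps were 307.8 against 217.5 (fell, then rose), 255.2 against 130.1 (fell and fell again) and 195.3 against 181.8 (rose and rose again). An excess thus also appears in probe sets that are not transient, so independent lists are a weak reference. A transient day 12 pattern may be present only as a hypothesis, and the excess is not an estimate of it.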
